A study of Mus musculus with 3 samples.

How the data were processed

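Single-cell RNA was measured in the trunks of mouse embryos at E13.5. Per the labels, a lentivirus carrying an EGFP reporter was injected into the amniotic fluid at E8.25, or E8 in the series summary, where it reaches the surface ectoderm and the neural plate. Trunks were later dissected away from skin, liver and gut, and EGFP-positive cells were sorted. The series has 1 group of 3 replicate libraries made with the 10x Chromium 3' v3 chemistry. The deposited matrices hold raw UMI counts (counts of distinct molecules per gene and barcode), which the authors made with Cell Ranger 3.0.1 on mm10 without any later normalisation or selection of cells. Each lists 6794880 barcodes and 27999 features, of which 27998 are Ensembl mouse genes and the other is the H2B-EGFP reporter. The matrices of replicates 1 and 3 were used, and that of replicate 2 was not analysed here. The labels do not say which embryos or how many went into each library, so the spread between libraries may be technical.

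Barcodes were taken as cells above a library's own UMI minimum, the 99th percentile of the top 6500 barcodes divided by 10, with at least 500 detected genes and at most 10% mitochondrial UMIs. Doublets were removed with Scrublet in scanpy 1.11.5, at an expected rate of 0.008 per 1000 cells. Genes were split into an even and an odd set by their identifiers. The even set, without the fixed gene lists and with the marker genes, 13930 genes in all, served for clustering. The other 14055 genes, including the 19 fixed gene lists, were tested, and 0 of them served for clustering. Clustering used log-normalised counts of 2056 genes, the 2000 most variable and the remaining markers, scaled within each library, 30 principal components, 15 shared neighbours and Leiden (leidenalg 0.10.2) at resolution 1. A cluster took the name of 1 of 22 marker lists when at least 3 of its markers led over all other clusters, by a log2 fold of at least 0.5 with detection in at least 10% of cells. Neural crest clusters were clustered again with 1000 variable genes and 20 components. Sub-clusters with at least 3 markers of an unrelated class and 1.5 times the UMIs were set apart as mixed. Crest cells with at least 3 UMIs of blood-cell genes were left out, 3 in each library, by a list made after such cells had been seen. The names end in -like, since they rest on markers alone, and the markers themselves are not results.

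UMI counts were summed per library and class, and sums, not cells, were tested with the edgeR 4.0.16 quasi-likelihood F test (R 4.3.3, TMM scaling, filterByExpr, library as a block). All named classes entered 1 fit to share its estimate of the spread. The planned minimum of 20 cells in each library gave 10 classes, 20 sums and 9 residual degrees of freedom. Comparisons with the chromaffin-like, bridge-like and melanoblast-like classes could not run at that minimum. They used at least 5 cells (17 classes, 34 sums, 16 residual degrees of freedom), a number chosen after the cell numbers were known and before any test. Most UMIs were from replicate 1 in the chromaffin-like and bridge-like sums and from replicate 3 in the melanoblast-like sums. After the filter, 7089 and 6956 genes were tested, with Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05, two-sided. Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and again with an estimated correlation, adjusted over 114 tests, 19 lists in 6 comparisons. This test asks whether a list moved relative to the other genes. Standard errors of log2 fold changes were taken from the F statistic, and values per library are CPM, UMI counts scaled to the same total. A fold against a class with 0 counts is a lower bound, computed with 3 counts over the class. With 1 to 3 counts, the ratio is given with its exact 95% counting interval. Shares of cells have exact Clopper-Pearson 95% intervals. Intervals and bounds cover counting error only.

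The genes named were chosen by a rule written before the data were examined, as were the gene lists, the markers, the comparisons and the tests, apart from the additions stated. From each list and direction it takes the member with the largest fold change that passed the test, moved the same way in both libraries and reached 20 CPM in the higher class in both. Further members, in order of mean expression, serve as examples, and how many were named was chosen with their values in view. Outside the lists it takes 4 genes in each direction with at least 50 CPM. A list with no such member is described by its most abundant one. Not every gene that the rule takes is named. Every gene named with a fold change that passed had the same direction in both libraries. Gene positions are from GENCODE vM21, where 27722 of the 27998 identifiers were found. The pipeline was tested on simulated data made from these sums, with 200 changed genes per comparison at 20 CPM or more. Changes of 2-fold were recovered for 85.1% of genes in sympathoblast-like against Schwann cell precursor-like cells, 92.5% against sensory neuron-like cells, and 76.1% in chromaffin-like against sympathoblast-like cells. The recovery was 56.7% in chromaffin-like against bridge-like cells, 43.3% in bridge-like and 13.4% in melanoblast-like against Schwann cell precursor-like cells. Unchanged genes made up 2.70 to 10.1% of the calls there. Alternatives were RLE size factors, no filter on low counts, no replicate block, DESeq2 1.42.0, a fit of only the 2 classes compared, at least 2000 detected genes, at most 5% mitochondrial UMIs, doublets retained, the odd genes for clustering, resolution 2 and each library left out. Added after the data were seen were no sub-clustering, mixed sub-clusters retained, the blood-cell filter off, at least 1000 UMIs in both libraries, no scaling within library, and other minimum numbers of cells. Other software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9.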

Results

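The data describe EGFP-sorted cells of the E13.5 mouse trunk, where the descendants of cells labelled before neurulation include the neural crest and its sympathoadrenal derivatives. There was 1 group of 3 replicates, and 2 of its libraries were analysed. Replicate 1 held 79342058 UMIs and replicate 3 held 83472956. The UMI minimum for a cell was 3081 in replicate 1 and 9829 in replicate 3. After all filters, 7426 cells with a median of 5541 UMIs remained in replicate 1, and 2296 cells with a median of 22794 in replicate 3. Doublet scores removed 8.04% of cells in replicate 1 and 0.390% in replicate 3. In the values that follow, ± is the SD of the 2 libraries for CPM and the SE for log2 fold changes.

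The first question was which cell types the sorted trunk cells contained. Neural crest classes other than sensory neurons made up 1062 cells in replicate 1 (14.3%, interval 13.5 to 15.1%) and 191 in replicate 3 (8.32%, interval 7.22 to 9.52%), a mean of 11.3% ± 4.23 (SD, n = 2). Schwann cell precursor-like cells, named for the glial progenitors along peripheral nerves, were 507 (6.83%) and 82 (3.57%) of the cells of replicates 1 and 3. Sympathoblast-like cells, named for the precursors of sympathetic neurons, were 228 (3.07%) and 80 (3.48%). Chromaffin-like cells, which make up the adrenal medulla, were 231 (3.11%) and 13 (0.566%). Bridge-like cells, named for an intermediate between Schwann cell precursors and chromaffin cells and with markers that included Tlx2, Htr3a and Dll3, were 85 (1.14%) and 10 (0.436%). Melanoblast-like cells, with Dct, Pmel, Mlana, Mitf and Kit, were 11 (0.148%) and 6 (0.261%). Sensory neuron-like cells were 478 (6.44%) and 82 (3.57%), spinal interneuron-like cells 846 (11.4%) and 160 (6.97%) and neural tube progenitor-like cells 102 (1.37%) and 30 (1.31%).

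Most sorted cells had markers of classes outside the neural plate and crest. They were 4153 cells in replicate 1 (55.9%, interval 54.8 to 57.1%) and 1643 in replicate 3 (71.6%, interval 69.7 to 73.4%). Mesenchyme-like cells were 1149 (15.5%) and 324 (14.1%), cartilage-like cells 1146 (15.4%) and 272 (11.8%), mural-like cells 542 (7.30%) and 153 (6.66%) and skeletal muscle-like cells 303 (4.08%) and 111 (4.83%). Epithelium-like cells with keratin transcripts were 873 (11.8%) and 745 (32.4%), although the skin had been dissected away. At clustering resolution 2 their share in replicate 3 was 17.7%, since 335 of them took the erythroid name. Small classes were mesothelium-like, 58 (0.781%) and 13 (0.566%), endothelium-like, 40 (0.539%) and 9 (0.392%), nephron-like, 33 (0.444%) and 10 (0.436%), and myeloid-like cells, 9 (0.121%) and 6 (0.261%). Mixed sub-clusters held 134 (1.80%) and 59 (2.57%) cells, and 651 (8.77%) and 131 (5.71%) had no name. All shares are of cells that passed the EGFP gate and each library's own UMI minimum, so they are not shares of the tissue.

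**Figure D1:**
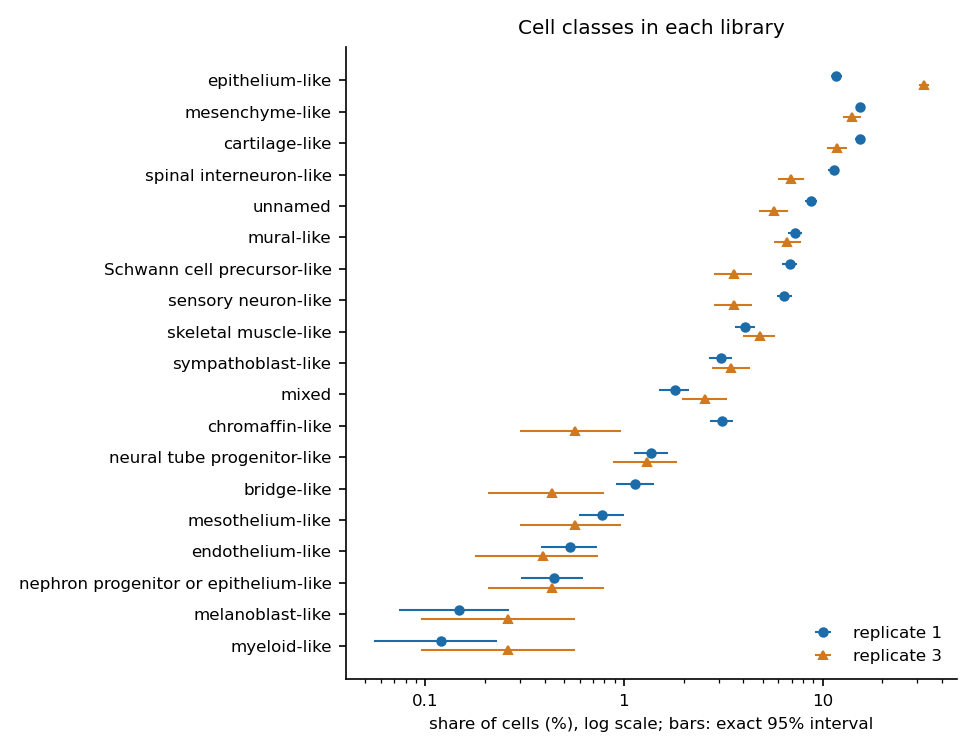
Share of cells in each class (%, logarithmic axis) in replicate 1 (circles) and replicate 3 (triangles), with exact 95% intervals as bars. The crest classes range from 0.148% for melanoblast-like to 6.83% for Schwann cell precursor-like cells in replicate 1, and epithelium-like cells differ most between the libraries in percentage points, at 11.8% and 32.4%.

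The reporter transcript was counted in each class to see where the label was carried. With 3000 UMIs drawn per cell, 83.7% of cells in replicate 1 and 75.0% in replicate 3 had an H2B-EGFP UMI. Among Schwann cell precursor-like cells the shares were 93.9% (interval 91.4 to 95.8%) and 84.1% (interval 74.4 to 91.3%), and among chromaffin-like cells 95.7% (interval 92.2 to 97.9%) and 84.6% (interval 54.6 to 98.1%). Sympathoblast-like cells had lower shares, 69.3% (interval 62.9 to 75.2%) and 51.2% (interval 39.8 to 62.6%), with median depths of 6548 and 23041 UMIs against 5555 and 19696 in Schwann cell precursor-like cells. In the classes outside the neural plate and crest the shares were 87.2% (interval 86.2 to 88.2%) and 76.3% (interval 74.2 to 78.4%). Myeloid-like cells, which arise outside the injected layers, had a reporter UMI in 44.4% (4 of 9 cells) and 16.7% (1 of 6), at median depths of 14077 and 35472 UMIs, which serves as background with wide intervals of 13.7 to 78.8% and 0.421 to 64.1%. Sympathoblast-like, endothelium-like, mesothelium-like and unnamed cells lay within those intervals in both libraries, so their shares are not separated from background. Barcodes with at most 100 UMIs, which hold free RNA, had 1028 CPM of the reporter in replicate 1 and 1392 CPM in replicate 3.

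**Figure D2:**
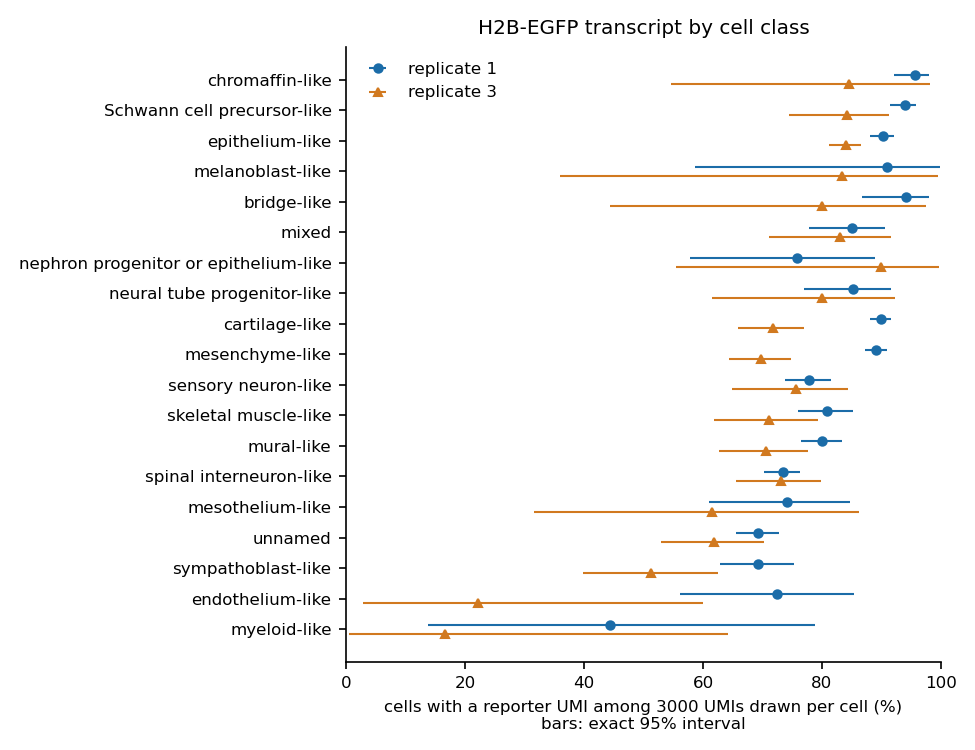
Share of cells in each class with at least 1 H2B-EGFP UMI among 3000 UMIs drawn per cell (%), in replicate 1 (circles) and replicate 3 (triangles), with exact 95% intervals as bars. Myeloid-like cells have the lowest share in replicate 3, 16.7%, and chromaffin-like cells have 95.7% in replicate 1.

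Sympathoblast-like and Schwann cell precursor-like cells were compared to ask what separates the sympathetic lineage from the glial progenitors of the same crest. Sympathoblast-like cells had the genes of catecholamine synthesis, secretory vesicles and neurites, and Schwann cell precursor-like cells those of glia, matrix and Notch signalling. Dbh, the enzyme that makes noradrenaline, stood at 882 ± 428 against 15.4 ± 14.1 CPM (log2 fold change 5.91 ± 0.40, adjusted p = 1.2e-08). Nefl, a neurofilament subunit, was at 3480.0 ± 553 against 23.7 ± 22.9 CPM (log2 fold change 7.17 ± 0.43, adjusted p = 2.1e-09). Ednrb, the endothelin receptor B, was at 7.25 ± 3.68 against 2057 ± 462 CPM (log2 fold change -8.25 ± 0.65, adjusted p = 2.9e-08). Fabp7, a fatty acid binding protein of glial progenitors, was at 3.16 ± 0.122 against 1856 ± 769 CPM (log2 fold change -9.24 ± 0.63, adjusted p = 6.4e-09). In mm10, the first ones are Dbh (ENSMUSG00000000889) on chromosome 2 from 27165233 to 27183200, Nefl (ENSMUSG00000022055) on chromosome 14 from 68083863 to 68089095 and Ednrb (ENSMUSG00000022122) on chromosome 14 from 103814625 to 103844402. Of 7089 tested genes, 3409 changed, 1960 (57.5%) higher and 1449 lower in sympathoblast-like cells. The higher share was 46.3 to 53.0% under settings that altered this fit.

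List medians are of the log2 fold changes of measured members, given again with genes of at most 3 counts in a class at their bound or ratio where that differs (at the bound). Lost or reversed, with a number of settings, says that a list no longer passed or changed sign under so many of the alternatives that gave a test. For lists past the threshold, the medians of replicates 1 and 3 are given (per library, from CPM + 1) where they differ more than 2 times. A list past the threshold with only 1 adjusted p given also passed with an estimated correlation. The catecholamine list had 10 of 12 higher and 0 lower (median 4.01, adjusted p = 2.7e-07). Its members included log2 fold changes of 6.73 ± 0.60 for Slc6a2, 3.10 ± 0.20 for Maoa, 3.33 ± 0.32 for Ddc and 4.97 ± 0.27 for Th, where Slc6a2 takes up noradrenaline and Th starts the pathway. Dense-core vesicle genes had 14 of 14 higher and 0 lower (median 4.22, adjusted p = 1.2e-11). Resp18 was 142-fold higher, 95% counting interval 48.0 to 690.0, beside a log2 fold change of 5.93 ± 0.42 for Pcsk1n. Neurite cytoskeleton genes had 15 of 15 higher and 0 lower (median 4.93, adjusted p = 8.0e-17). Nefm had a log2 fold change of 7.03 ± 0.46. Neuronal differentiation regulators had 13 of 15 higher and 0 lower (median 3.91, adjusted p = 4.2e-12). Insm1 was 346-fold higher, 95% counting interval 95.4 to 2870.0, with a log2 fold change of 1.11 ± 0.16 for Sox4. The synaptic vesicle list had 14 of 14 higher and 0 lower (median 3.39, adjusted p = 2.5e-15), with log2 fold changes of 7.03 ± 0.48 for Cplx1 and 1.48 ± 0.16 for Vamp2. Ion channels and transmitter receptors had 12 of 14 higher and 0 lower (median 4.16, or 4.35 at the bound, adjusted p = 3.0e-10). Cacna2d1, a calcium channel subunit, had a log2 fold change of 3.59 ± 0.25. Neuropeptide genes had 5 of 11 higher and 1 lower (median 2.32, or 2.10 at the bound, adjusted p = 0.30). Sst was at least 86.3-fold higher and among the leading genes of a sub-cluster of 22 and 1 of these cells, with a log2 fold change of 2.32 ± 0.47 for Npy.

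Glial and neural crest genes had 1 of 16 higher and 14 lower (median -4.72, or -4.50 at the bound, adjusted p = 7.0e-13). They included a log2 fold change of -3.18 ± 0.20 for Zeb2, while Tfap2b, a crest transcription factor, had a log2 fold change of 4.08 ± 0.52. Basement membrane and matrix genes had 0 of 13 higher and 13 lower (median -6.11, adjusted p = 5.6e-18). Nid2 was at least 125-fold lower, with a log2 fold change of -6.94 ± 0.60 for Sparc. Notch pathway genes had 2 of 13 higher and 10 lower (median -4.01, or -3.83 at the bound, adjusted p = 1.4e-06). Heyl was 239-fold lower, 95% counting interval 42.7 to 9490.0, Notch1 had a log2 fold change of -6.34 ± 0.36, and Hes6, a Notch antagonist, had a log2 fold change of 0.97 ± 0.29. Growth factor receptors had 3 of 14 higher and 7 lower (median -1.64, adjusted p = 0.0091, adjusted p = 0.26 with an estimated correlation, lost under 1 of 14 settings). Ret, the receptor of the GDNF family, had a log2 fold change of 6.30 ± 0.55, and Erbb3 was 273-fold lower, 95% counting interval 75.2 to 2260.0. Dissociation stress genes, which rise when tissue is taken apart, had 2 of 12 higher and 7 lower (median -1.13, adjusted p = 0.11), with log2 fold changes of 0.70 ± 0.24 for Dusp1, -1.80 ± 0.29 for Junb and -1.11 ± 0.31 for Fos.

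S phase genes had 13 of 15 higher and 0 lower (median 1.08, adjusted p = 5.1e-05, adjusted p = 0.090 with an estimated correlation), with log2 fold changes of 2.22 ± 0.19 for Rrm2 and 1.16 ± 0.11 for Mcm7. G2/M phase genes had 14 of 15 higher and 0 lower (median 1.10, 1.54 and 0.66 per library, adjusted p = 0.0012, adjusted p = 0.49 with an estimated correlation, lost under 8 of 14 settings), with a log2 fold change of 1.64 ± 0.19 for Ube2c. Neuroblastoma and paraganglioma genes had 10 of 14 higher and 1 lower (median 0.77, adjusted p = 0.018, adjusted p = 0.090 with an estimated correlation), with log2 fold changes of 0.41 ± 0.08 for Atrx and -0.77 ± 0.19 for Nf1. Trunk Hox genes went both ways, with 5 of 18 higher and 3 lower (median 0.46, adjusted p = 0.51). Members of the Hoxc cluster were higher, with log2 fold changes of 3.52 ± 0.41 for Hoxc8 and 2.36 ± 0.26 for Hoxc9, and Hoxb9 had a log2 fold change of -3.25 ± 0.50. Imprinted growth genes had 4 of 12 higher and 6 lower (median -0.46, mean 0.04, adjusted p = 0.89), with log2 fold changes of 2.48 ± 0.31 for Dlk1 and -2.62 ± 0.33 for Mest. Hypoxia and glycolysis genes had 4 of 12 higher and 3 lower (median -0.07, mean 0.36, adjusted p = 0.89), with log2 fold changes of 6.22 ± 0.44 for Egln3 and -3.55 ± 0.27 for Ddit4. Glucocorticoid response genes had 3 of 7 higher and 1 lower (median 1.14, adjusted p = 0.67), with a log2 fold change of 1.14 ± 0.15 for Tsc22d3. Outside the lists, Smpd3 was 164-fold higher, 95% counting interval 44.9 to 1360.0, Bmp3 was 155-fold higher, 95% counting interval 42.4 to 1290.0, with log2 fold changes of 7.05 ± 0.38 for Vstm2l and 7.01 ± 0.43 for Pou2f2. Genes with 0 counts in sympathoblast-like cells were lower by at least 143-fold for Col20a1, 106-fold for Npr3, 105-fold for Vgll3 and 102-fold for Plekha4. Adjusted over the list alone, higher and lower counts differed for neuronal differentiation regulators (14 and 0), neuroblastoma and paraganglioma genes (11 and 1) and dissociation stress genes (2 and 8). Under some of the 15 other settings, adjusted p was 0.05 or more, for Sox4, Vamp2, Fos, Mcm7, Ube2c and Hoxb9 under 1, Hes6 under 3, Atrx under 5 and Dusp1 under 8. Without the replicate block 2000 genes changed.

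Bridge-like cells were compared with Schwann cell precursor-like cells to ask what changes as glial progenitors leave towards the adrenal medulla. Bridge-like cells had more of Cdkn1c and of the neuroendocrine regulator Insm1, and less of 4 glial and 2 matrix genes. No catecholamine gene passed the test over all genes, but the list was higher under 5 of 6 settings with new clusters. Cdkn1c, an imprinted inhibitor of cyclin-dependent kinases, stood at 6185 ± 1936 against 855 ± 178 CPM (log2 fold change 2.85 ± 0.37, adjusted p = 7.2e-05). Insm1 was 212-fold higher, 95% counting interval 56.7 to 1780.0, and Sox11 had a log2 fold change of 1.33 ± 0.25. Cck, a peptide hormone gene, had a log2 fold change of 8.08 ± 1.12, and Mfng, a glycosyltransferase that modifies Notch, had a log2 fold change of 3.73 ± 0.61. Their mm10 positions are Cdkn1c (ENSMUSG00000037664) on chromosome 7 from 143458339 to 143461050, Insm1 (ENSMUSG00000068154) on chromosome 2 from 146221921 to 146225020 and Cck (ENSMUSG00000032532) on chromosome 9 from 121489824 to 121495694. Of 6956 tested genes, 200 changed, 67 higher and 133 lower in bridge-like cells. The higher ones were 33.5% of these (30.6 to 61.5% under other settings). These values depend on the clusters. Under all 6 tested settings with new ones, G2/M phase genes were lower and dense-core genes higher, and synaptic genes higher under 5. The other settings kept the clusters.

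Glial and neural crest genes had 1 of 16 higher and 4 lower (median -0.69, adjusted p = 0.0036, adjusted p = 0.27 with an estimated correlation, lost under 1 of 13 settings). They included log2 fold changes of -2.03 ± 0.43 for Fabp7 and -1.44 ± 0.31 for Ttyh1, while Sox8 had a log2 fold change of 1.93 ± 0.47. Fabp7 and Ttyh1 were also leading genes of a sub-cluster within the Schwann cell precursor-like class. Basement membrane and matrix genes had 0 of 13 higher and 2 lower (median -0.93, adjusted p = 8.0e-04, adjusted p = 0.33 with an estimated correlation), with log2 fold changes of -1.59 ± 0.40 for Nid1 and -1.23 ± 0.31 for Col4a2. Dissociation stress genes had 0 of 12 higher and 3 lower (median -0.95, adjusted p = 1.8e-06, adjusted p = 0.090 with an estimated correlation, lost under 3 of 13 settings), with a log2 fold change of -2.12 ± 0.37 for Egr1. Growth factor receptors had 1 of 14 higher and 1 lower (median -0.82, or -0.73 at the bound, adjusted p = 0.029, adjusted p = 0.35 with an estimated correlation, lost under 2 of 13 settings), with a log2 fold change of -1.81 ± 0.28 for Gfra3. The Notch pathway had 2 of 13 higher and 1 lower (median -0.37, or -0.42 at the bound, mean 0.01, test direction up, adjusted p = 0.77), with log2 fold changes of 1.82 ± 0.33 for Hes6 and -3.20 ± 0.76 for Hey2. Neuronal differentiation regulators had 2 of 15 higher and 0 lower (median 0.13, or 0.41 at the bound, mean -0.54, 0.01 and 0.00 per library, adjusted p = 0.0088, adjusted p = 0.35 with an estimated correlation, reversed under 2 of 13 settings). Neurite cytoskeleton genes had 1 of 15 higher and 0 lower (median 0.36, mean -0.13, 0.19 and 0.92 per library, adjusted p = 0.028, adjusted p = 0.49 with an estimated correlation, lost under 2 of 13 settings and reversed under 1), with a log2 fold change of 1.70 ± 0.25 for Dpysl3. Ion channels and transmitter receptors had 0 of 14 higher and 0 lower (median 0.71, or 0.72 at the bound, 0.00 and 0.00 per library, adjusted p = 0.0091, adjusted p = 0.090 with an estimated correlation, lost under 1 of 12 settings and reversed under 1). Cacna1a, the most abundant, had a log2 fold change of -0.37 ± 0.59, which did not pass.

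The catecholamine list had 0 of 12 higher and 0 lower (median -0.39, or -0.26 at the bound, adjusted p = 0.89, but reversed and past the test under 5 of 13 settings). Dense-core vesicle genes had 2 of 14 higher and 0 lower (median -0.90, or -0.20 at the bound, test direction up, adjusted p = 0.42, but reversed and past the test under 6 of 13 settings), with log2 fold changes of 2.03 ± 0.37 for Cadps and 1.93 ± 0.42 for Scg5. The synaptic vesicle list had 0 of 14 higher and 0 lower (median -0.39, test direction up, adjusted p = 0.931, but reversed and past the test under 5 of 13 settings). Vamp2, at 41.5 ± 20.1 against 62.2 ± 27.3 CPM, did not pass. S phase genes had 2 of 15 higher and 0 lower (median 0.26, 0.12 and 0.46 per library, adjusted p = 4.9e-04, adjusted p = 0.20 with an estimated correlation, lost under 4 of 13 settings and reversed under 2), with log2 fold changes of 0.78 ± 0.20 for Slbp and 0.67 ± 0.18 for Mcm7. G2/M phase genes had 0 of 15 higher and 0 lower (median 0.09, adjusted p = 0.52, but reversed and past the test under 6 of 13 settings). Top2a, at 309 ± 45.5 against 286 ± 40.2 CPM, did not pass. Neuropeptide genes had 1 of 11 higher and 0 lower (median 0.03, or 0.14 at the bound, adjusted p = 0.17), and imprinted growth genes 1 of 12 higher and 0 lower (median 0.14, or -0.02 at the bound, adjusted p = 0.63). Neuroblastoma and paraganglioma genes had 1 of 14 higher and 0 lower (median -0.05, or -0.09 at the bound, mean 0.21, test direction up, adjusted p = 0.19). Atrx, at 301 ± 0.283 against 305 ± 56.5 CPM, did not pass. Trunk Hox genes had 0 of 18 higher and 1 lower (median -0.09, or -0.02 at the bound, test direction up, adjusted p = 0.77), with a log2 fold change of -2.12 ± 0.58 for Hoxa9, against 0.27 with resolution 2. Hypoxia and glycolysis genes had 0 of 12 higher and 1 lower (median -0.20, adjusted p = 0.87, but reversed and past the test under 1 of 13 settings), with a log2 fold change of -1.61 ± 0.40 for Ddit4. Glucocorticoid response genes had 0 of 7 higher and 0 lower (median -0.51, or -0.15 at the bound, adjusted p = 0.90). Tsc22d3, at 46.8 ± 5.50 against 39.6 ± 2.74 CPM, did not pass.

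Outside the lists, the higher genes included log2 fold changes of 2.88 ± 0.37 for Id1, 2.38 ± 0.37 for C1ql1, 2.15 ± 0.20 for Ckb and 2.10 ± 0.36 for Tbx2, where Id1 is an inhibitor of basic helix-loop-helix factors and Tbx2 a T-box factor. Lower genes outside the lists included log2 fold changes of -4.49 ± 0.72 for Sncg, -3.53 ± 0.65 for Entpd2, -3.51 ± 0.66 for Plekha4 and -3.18 ± 0.63 for Ank3. Adjusted over the list alone, higher and lower counts differed for catecholamine synthesis and transport (1 and 0), growth factor receptors (1 and 3), ion channels and transmitter receptors (3 and 0), neuroblastoma and paraganglioma genes (3 and 0), glial and neural crest genes (1 and 9), Notch pathway (3 and 4), basement membrane and matrix (0 and 7), trunk Hox genes (1 and 1), S phase genes (3 and 0), imprinted growth genes (1 and 2) and dissociation stress genes (0 and 6). Under some of the 13 or 14 other settings that tested the gene, adjusted p was 0.05 or more, for Cck, Hes6, Dpysl3, Cadps, Scg5, C1ql1, Tbx2, Sncg and Plekha4 under 1, Sox11, Gfra3 and Ank3 under 2, Nid1, Col4a2 and Entpd2 under 3, Fabp7, Ttyh1, Egr1 and Hey2 under 4, Ddit4 under 5, Sox8 under 6, Slbp and Mcm7 under 8 and Hoxa9 under 9. Under other class definitions 58 to 805 genes changed.

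Chromaffin-like cells were compared with bridge-like cells to ask what is gained between the intermediate and the endocrine cell. Chromaffin-like cells had the catecholamine, dense-core vesicle, neurite and synaptic genes, and bridge-like cells those of glia and S phase. Matrix and G2/M phase genes passed only at the preset correlation (adjusted p = 0.076 for each with an estimated correlation), and the G2/M median turned to 0.44 with at least 2000 detected genes. Th, tyrosine hydroxylase, stood at 1457 ± 1487 against 5.92 ± 8.37 CPM (log2 fold change 7.63 ± 0.51, adjusted p = 6.9e-09), with 2508 and 405 CPM in the chromaffin-like cells of replicates 1 and 3. Dlk1, an imprinted Notch ligand homologue, was at 2224 ± 851 against 14.0 ± 8.82 CPM (log2 fold change 7.09 ± 0.60, adjusted p = 1.0e-08). Cdkn1c was at 1572 ± 30.4 against 6185 ± 1936 CPM (log2 fold change -1.96 ± 0.36, adjusted p = 3.0e-04). Serpine2, a secreted protease inhibitor, was at 69.2 ± 27.1 against 568 ± 7.64 CPM (log2 fold change -3.20 ± 0.31, adjusted p = 8.9e-08). Positions in mm10 are Th (ENSMUSG00000000214) on chromosome 7 from 142892752 to 142931128 and Dlk1 (ENSMUSG00000040856) on chromosome 12 from 109452823 to 109463336. Of 6956 tested genes, 1431 changed, 728 higher and 703 lower in chromaffin-like cells. The higher ones were 50.9% of these (44.7 to 59.5% under other settings).

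The catecholamine list had 9 of 12 higher and 0 lower (median 5.17, or 3.04 at the bound, adjusted p = 4.8e-10). Cyb561 was at least 143-fold higher, and Dbh had a log2 fold change of 7.95 ± 0.72. Dense-core vesicle genes had 11 of 14 higher and 0 lower (median 5.32, or 3.76 at the bound, adjusted p = 1.2e-11). Resp18 was at least 78.8-fold higher, with a log2 fold change of 6.39 ± 0.62 for Pcsk1n. Neurite cytoskeleton genes had 14 of 15 higher and 0 lower (median 3.13, adjusted p = 2.6e-10), with a log2 fold change of 4.94 ± 0.75 for Stmn2. The synaptic vesicle list had 11 of 14 higher and 0 lower (median 3.26, or 2.63 at the bound, adjusted p = 5.4e-12). Rab3c was at least 20.1-fold higher, and Vamp2 had a log2 fold change of 2.25 ± 0.28. Neuronal differentiation regulators had 8 of 15 higher and 1 lower (median 3.0, or 2.80 at the bound, adjusted p = 9.6e-06, adjusted p = 0.090 with an estimated correlation, lost under 5 of 13 settings). St18 was at least 33.5-fold higher, with a log2 fold change of 3.0 ± 0.54 for Elavl3. Ion channels and transmitter receptors had 6 of 14 higher and 0 lower (median 2.41, or 2.0 at the bound, adjusted p = 1.2e-04, adjusted p = 0.051 with an estimated correlation). Scn3a was at least 18.1-fold higher, with a log2 fold change of 3.60 ± 0.37 for Cacna2d1. Dissociation stress genes had 8 of 12 higher and 0 lower (median 1.91, or 1.83 at the bound, adjusted p = 2.8e-06, adjusted p = 0.097 with an estimated correlation), with a log2 fold change of 3.15 ± 0.55 for Fosb. Neuropeptide genes had 2 of 11 higher and 1 lower (median -0.02, or 0.33 at the bound, mean 0.62, test direction up, adjusted p = 0.77), with a log2 fold change of 5.71 ± 0.75 for Npy.

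Glial and neural crest genes had 1 of 16 higher and 13 lower (median -2.81, adjusted p = 2.7e-10). Tfap2a was 35.0-fold lower, 95% counting interval 11.2 to 176, with a log2 fold change of -3.16 ± 0.54 for Fabp7, while Tfap2b had a log2 fold change of 2.83 ± 0.84. Basement membrane and matrix genes had 0 of 13 higher and 12 lower (median -2.60, -3.63 and -1.50 per library, adjusted p = 1.7e-09, adjusted p = 0.076 with an estimated correlation), with log2 fold changes of -3.67 ± 0.64 for Nid2 and -2.28 ± 0.78 for Sparc. The Notch pathway had 1 of 13 higher and 5 lower (median -1.56, or -1.40 at the bound, -1.44 and -0.50 per library, adjusted p = 0.0054, adjusted p = 0.11 with an estimated correlation, lost under 1 of 13 settings). Heyl was 27.1-fold lower, 95% counting interval 8.52 to 138, and Notch1 had a log2 fold change of -2.06 ± 0.43. Mfng had a log2 fold change of 1.24 ± 0.41, against -0.06 to -1.20 under settings with new clusters. Growth factor receptors had 1 of 14 higher and 7 lower (median -1.27, or -1.69 at the bound, adjusted p = 0.017, adjusted p = 0.31 with an estimated correlation, lost under 5 of 13 settings), with log2 fold changes of 3.20 ± 0.63 for Ntrk3 and -3.35 ± 0.62 for Erbb3. S phase genes had 0 of 15 higher and 13 lower (median -1.40, adjusted p = 1.5e-10), with a log2 fold change of -2.03 ± 0.26 for Tyms. G2/M phase genes had 0 of 15 higher and 15 lower (median -2.98, adjusted p = 3.1e-13, adjusted p = 0.076 with an estimated correlation, lost under 3 of 13 settings and reversed under 1), with a log2 fold change of -3.88 ± 0.58 for Cenpe.

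Imprinted growth genes went both ways, with 3 of 12 higher and 2 lower (median -0.05, mean 0.87, test direction up, adjusted p = 0.31), and Meg3 had a log2 fold change of 4.57 ± 0.49. Hypoxia and glycolysis genes had 4 of 12 higher and 1 lower (median 0.19, adjusted p = 0.34), with log2 fold changes of 2.87 ± 0.58 for Vegfa and -1.07 ± 0.20 for Eno1. Neuroblastoma and paraganglioma genes had 2 of 14 higher and 0 lower (median 0.10, or 0.21 at the bound, adjusted p = 0.70). Epas1 was 214-fold higher, 95% counting interval 59.0 to 1770.0. It encodes a hypoxia-inducible factor. Trunk Hox genes had 1 of 18 higher and 1 lower (median 0.82, or 0.80 at the bound, adjusted p = 0.33). Hoxa9 had a log2 fold change of 2.24 ± 0.61, against -0.17 to -0.52 under some settings with new clusters, and Hoxb9 had -1.95 ± 0.44. Glucocorticoid response genes had 1 of 7 higher and 0 lower (median 1.16, or -0.01 at the bound, adjusted p = 0.51). Tsc22d3, at 53.2 ± 18.5 against 46.8 ± 5.50 CPM, did not pass. Genes outside the lists at 0 counts in bridge-like cells were higher by at least 71.7-fold for Kcnk3, 29.3-fold for Doc2b, 21.2-fold for Kif5a and 21.3-fold for Shox2. Those lower outside the lists included log2 fold changes of -4.81 ± 0.54 for Wwtr1, -4.75 ± 0.66 for Cryab, -4.46 ± 0.64 for Arhgef26 and -4.03 ± 0.70 for Gas7. Adjusted over the list alone, higher and lower counts differed for catecholamine synthesis and transport (10 and 0), neuronal differentiation regulators (10 and 1), synaptic vesicle (12 and 0), ion channels and transmitter receptors (7 and 0), neuropeptides (2 and 2), neuroblastoma and paraganglioma genes (1 and 0), Notch pathway (1 and 6), S phase genes (0 and 15) and dissociation stress genes (9 and 0). Under some of the 13 or 14 other settings that tested the gene, adjusted p was 0.05 or more, for Nid2, Heyl, Mfng, Ntrk3, Eno1, Hoxa9, Cryab and Gas7 under 1, Tfap2a and Fabp7 under 2, St18, Notch1, Erbb3, Cenpe and Hoxb9 under 3, Vegfa under 4, Elavl3 under 5, Tfap2b under 6 and Sparc under 8.

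Chromaffin-like cells were compared with sympathoblast-like cells to ask how the endocrine and the neuronal branch of the sympathoadrenal lineage differ. Chromaffin-like cells had fewer transcripts of S phase genes and more of Th and the vesicular monoamine transporter Slc18a2. Of 10 lists past the test, only the S phase and Notch lists passed with an estimated correlation, where the other 8 had an adjusted p of 0.052 to 0.48. Notch, glial and matrix medians were all larger in replicate 3, with 13 chromaffin-like cells. Slc18a2 stood at 292 ± 132 against 58.4 ± 7.65 CPM (log2 fold change 2.30 ± 0.32, adjusted p = 1.6e-05). Nefm was at 540.0 ± 45.5 against 4550.0 ± 306 CPM (log2 fold change -3.11 ± 0.38, adjusted p = 1.5e-06). Top2a, the topoisomerase of dividing cells, was at 63.4 ± 2.90 against 609 ± 172 CPM (log2 fold change -3.28 ± 0.38, adjusted p = 5.4e-07). Epas1 was at 351 ± 364 against 28.9 ± 23.3 CPM (log2 fold change 3.60 ± 0.50, adjusted p = 9.0e-06), with 608 and 93.3 CPM in the chromaffin-like cells of replicates 1 and 3. Mm10 positions are Slc18a2 (ENSMUSG00000025094) on chromosome 19 from 59260896 to 59296012 and Epas1 (ENSMUSG00000024140) on chromosome 17 from 86753700 to 86833410. Of 6956 tested genes, 1874 changed, 1001 higher and 873 lower in chromaffin-like cells. The higher ones were 53.4% of these (42.0 to 62.5% under other settings).

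S phase genes had 0 of 15 higher and 15 lower (median -1.91, adjusted p = 1.9e-15), with a log2 fold change of -3.06 ± 0.35 for Rrm2. G2/M phase genes had 0 of 15 higher and 15 lower (median -3.73, adjusted p = 5.3e-16, adjusted p = 0.052 with an estimated correlation), with a log2 fold change of -4.69 ± 0.52 for Ube2c. Neurite cytoskeleton genes had 1 of 15 higher and 13 lower (median -1.80, adjusted p = 1.2e-06, adjusted p = 0.097 with an estimated correlation), with a log2 fold change of -3.74 ± 0.32 for Stmn4. Neuronal differentiation regulators had 2 of 15 higher and 7 lower (median -0.85, adjusted p = 0.12), with log2 fold changes of 3.40 ± 0.45 for St18, -3.77 ± 0.36 for Elavl2 and -1.56 ± 0.27 for Sox4. The synaptic vesicle list had 1 of 14 higher and 2 lower (median 0.17, mean -0.26, test direction down, adjusted p = 0.67), with log2 fold changes of 1.62 ± 0.24 for Syp and -4.04 ± 0.40 for Cplx1. Ion channels and transmitter receptors had 1 of 14 higher and 5 lower (median -0.42, or -0.59 at the bound, adjusted p = 0.038, adjusted p = 0.27 with an estimated correlation, lost under 10 of 14 settings), with log2 fold changes of 0.87 ± 0.20 for Cacna2d1 and -1.94 ± 0.49 for Scn9a. Neuroblastoma and paraganglioma genes had 1 of 14 higher and 7 lower (median -0.48, adjusted p = 0.018, adjusted p = 0.059 with an estimated correlation, lost under 2 of 14 settings), with a log2 fold change of -1.24 ± 0.38 for Ret. Growth factor receptors had 4 of 14 higher and 3 lower (median -0.49, or -0.38 at the bound, mean 0.24, adjusted p = 0.77), with log2 fold changes of 4.41 ± 0.82 for Ednrb and -3.30 ± 0.30 for Gfra3. Neuropeptide genes had 3 of 11 higher and 3 lower (median -2.53, or 0.57 at the bound, adjusted p = 0.76). Vip was 189-fold lower, 95% counting interval 33.7 to 7490.0, and Npy had a log2 fold change of 1.23 ± 0.44.

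The catecholamine list had 7 of 12 higher and 2 lower (median 0.87, adjusted p = 0.22), with log2 fold changes of 1.11 ± 0.38 for Dbh, 2.18 ± 0.27 for Th and -2.41 ± 0.26 for Maoa. Dense-core vesicle genes had 5 of 14 higher and 0 lower (median 0.05, adjusted p = 0.58), with log2 fold changes of 2.10 ± 0.36 for Scg2 and 1.39 ± 0.36 for Syt1. The Notch pathway had 8 of 13 higher and 0 lower (median 2.50, or 2.42 at the bound, 0.77 and 2.27 per library, adjusted p = 2.1e-04), with a log2 fold change of 3.20 ± 0.38 for Mfng. Glial and neural crest genes had 6 of 16 higher and 1 lower (median 1.05, 0.61 and 1.51 per library, adjusted p = 0.017, adjusted p = 0.37 with an estimated correlation, lost under 2 of 14 settings), with log2 fold changes of 4.18 ± 0.89 for Fabp7 and -1.16 ± 0.34 for Pmp22. Basement membrane and matrix genes had 6 of 13 higher and 0 lower (median 2.18, 0.69 and 3.78 per library, adjusted p = 7.7e-04, adjusted p = 0.33 with an estimated correlation, lost under 1 of 14 settings). Sparc, at 303 ± 349 against 24.7 ± 13.6 CPM, had a log2 fold change of 3.61 ± 0.93. Imprinted growth genes had 6 of 12 higher and 0 lower (median 0.90, 0.61 and 1.31 per library, adjusted p = 0.018, adjusted p = 0.48 with an estimated correlation, lost under 1 of 14 settings), with log2 fold changes of 2.94 ± 0.62 for H19 and 1.98 ± 0.42 for Meg3. Dissociation stress genes had 10 of 12 higher and 0 lower (median 1.95, or 1.94 at the bound, adjusted p = 5.1e-05, adjusted p = 0.17 with an estimated correlation), with a log2 fold change of 2.60 ± 0.42 for Fosb. Hypoxia and glycolysis genes had 4 of 12 higher and 2 lower (median 0.55, adjusted p = 0.17), with log2 fold changes of 2.32 ± 0.46 for Ddit4 and -5.51 ± 0.61 for Egln3. Glucocorticoid response genes had 3 of 7 higher and 2 lower (median -0.24, mean 0.25, adjusted p = 0.90). Nr3c1, the glucocorticoid receptor, had a log2 fold change of 1.08 ± 0.32, against a log2 fold change of -0.71 ± 0.21 for Tsc22d3. Trunk Hox genes had 4 of 18 higher and 3 lower (median 0.03, adjusted p = 0.970, but reversed and past the test under 1 of 14 settings), with a log2 fold change of 2.68 ± 0.41 for Hoxb8, against -0.08 with at least 2000 detected genes, and with a log2 fold change of -3.16 ± 0.63 for Hoxc8.

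Outside the lists, the higher genes included log2 fold changes of 4.66 ± 0.75 for Igfbp5, 4.56 ± 0.45 for Ccnd2, 4.13 ± 0.57 for C2cd4b and 4.10 ± 0.51 for Fam46a. Among the lower ones were log2 fold changes of -4.19 ± 0.46 for Sncg, -4.06 ± 0.41 for Kif11, -3.96 ± 0.32 for Pbk and -3.78 ± 0.43 for Tacc3, the last 3 of them genes of mitosis. Adjusted over the list alone, higher and lower counts differed for catecholamine synthesis and transport (8 and 2), neuronal differentiation regulators (3 and 7), neuroblastoma and paraganglioma genes (1 and 8), glial and neural crest genes (7 and 2), Notch pathway (9 and 0), basement membrane and matrix (9 and 0), hypoxia and glycolysis genes (5 and 2) and dissociation stress genes (12 and 0). Under some of the 15 other settings, adjusted p was 0.05 or more, for Sox4, Scn9a, Vip, Th, Fabp7, Meg3 and Nr3c1 under 1, Cacna2d1, Ret, Syt1, Sparc, H19 and Hoxb8 under 2, Tsc22d3 under 3, Pmp22 under 4 and Npy and Dbh under 7.

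Sympathoblast-like cells were compared with sensory neuron-like cells to separate what is particular to sympathetic precursors from what they share with another crest-derived neuron. Sympathoblast-like cells had more transcripts of cell cycle genes. They also had more of most catecholamine genes, where the list had an adjusted p = 0.090 with an estimated correlation. Ccnd1, cyclin D1, stood at 3199 ± 1049 against 74.1 ± 30.0 CPM (log2 fold change 5.38 ± 0.31, adjusted p = 8.3e-10). Dbh was at 882 ± 428 against 46.0 ± 41.3 CPM (log2 fold change 4.42 ± 0.32, adjusted p = 2.5e-08). Gal, which encodes galanin, was at 18.4 ± 4.39 against 896 ± 140.1 CPM (log2 fold change -5.61 ± 0.14, adjusted p = 3.7e-13). Positions are, in mm10, Ccnd1 (ENSMUSG00000070348) on chromosome 7 from 144929931 to 144939925 and Gal (ENSMUSG00000024907) on chromosome 19 from 3409915 to 3414544. Of 7089 tested genes, 2784 changed, 1324 (47.6%) higher and 1460 lower in sympathoblast-like cells. The higher share was 35.0 to 47.3% under settings that altered this fit.

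S phase genes had 15 of 15 higher and 0 lower (median 2.99, adjusted p = 5.2e-50), with a log2 fold change of 4.99 ± 0.23 for Rrm2. G2/M phase genes had 15 of 15 higher and 0 lower (median 4.21, adjusted p = 3.4e-44), with a log2 fold change of 4.56 ± 0.22 for Ube2c. The catecholamine list had 8 of 12 higher and 2 lower (median 2.84, adjusted p = 5.1e-05, adjusted p = 0.090 with an estimated correlation), with log2 fold changes of 4.92 ± 0.44 for Slc6a2, 3.45 ± 0.19 for Maoa and -0.54 ± 0.17 for Qdpr. Neuroblastoma and paraganglioma genes had 6 of 14 higher and 0 lower (median 0.40, adjusted p = 0.0094, adjusted p = 0.094 with an estimated correlation), with log2 fold changes of 3.73 ± 0.26 for Lmo1 and 0.93 ± 0.07 for Atrx. Neuronal differentiation regulators had 3 of 15 higher and 9 lower (median -0.77, adjusted p = 0.024, adjusted p = 0.48 with an estimated correlation, lost under 5 of 14 settings), with log2 fold changes of 2.47 ± 0.29 for Insm1 and -5.05 ± 0.52 for Nhlh1. The synaptic vesicle list had 3 of 14 higher and 8 lower (median -0.78, adjusted p = 0.041, adjusted p = 0.40 with an estimated correlation, lost under 1 of 14 settings), with log2 fold changes of 1.12 ± 0.23 for Rab3c and -1.77 ± 0.14 for Rab3a. Neuropeptide genes had 3 of 11 higher and 4 lower (median -1.31, -0.06 and -1.37 per library, adjusted p = 0.0088, adjusted p = 0.076 with an estimated correlation, lost under 9 of 14 settings). Cck was 161-fold lower, 95% counting interval 28.7 to 6360.0, with log2 fold changes of 5.76 ± 0.62 for Vip and 3.13 ± 0.46 for Npy. The Notch pathway had 0 of 13 higher and 7 lower (median -3.06, or -2.16 at the bound, adjusted p = 0.0058, adjusted p = 0.090 with an estimated correlation), with a log2 fold change of -2.16 ± 0.28 for Mfng. Basement membrane and matrix genes had 0 of 13 higher and 8 lower (median -2.42, -1.09 and -3.01 per library, adjusted p = 0.0091, adjusted p = 0.48 with an estimated correlation, lost under 2 of 14 settings), with a log2 fold change of -2.45 ± 0.60 for Sparc.

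Ion channels and transmitter receptors had 2 of 14 higher and 6 lower (median -0.50, adjusted p = 0.055). P2rx3 encodes an ATP-gated channel. P2rx3 was 334-fold lower, 95% counting interval 59.7 to 13200.0, with a log2 fold change of 1.13 ± 0.24 for Chrna3. Growth factor receptors had 4 of 14 higher and 7 lower (median -1.55, adjusted p = 0.15), with a log2 fold change of 1.28 ± 0.33 for Ret. Dense-core vesicle genes had 5 of 14 higher and 3 lower (median 0.19, adjusted p = 0.53), with log2 fold changes of 2.90 ± 0.28 for Rab3b and -2.74 ± 0.52 for Pcsk2. Neurite cytoskeleton genes had 1 of 15 higher and 8 lower (median -0.70, adjusted p = 0.17), with log2 fold changes of 0.56 ± 0.17 for Crmp1 and -2.05 ± 0.22 for Mapt. Glial and neural crest genes had 2 of 16 higher and 7 lower (median -1.24, or -1.06 at the bound, adjusted p = 0.11), with log2 fold changes of 4.24 ± 0.47 for Tfap2b and -4.68 ± 0.71 for Ttyh1. Trunk Hox genes had 4 of 18 higher and 9 lower (median -0.82, adjusted p = 0.069), with log2 fold changes of 2.0 ± 0.30 for Hoxc8 and -2.68 ± 0.41 for Hoxb8. Imprinted growth genes had 4 of 12 higher and 1 lower (median 0.30, adjusted p = 0.070), with a log2 fold change of 2.82 ± 0.30 for Dlk1. Hypoxia and glycolysis genes had 1 of 12 higher and 5 lower (median -0.28, mean 0.13, adjusted p = 0.67), with log2 fold changes of 5.66 ± 0.36 for Egln3 and -0.90 ± 0.28 for Pfkp. Glucocorticoid response genes had 2 of 7 higher and 0 lower (median 0.28, adjusted p = 0.44), with a log2 fold change of 2.28 ± 0.31 for Nr3c1. Dissociation stress genes had 6 of 12 higher and 1 lower (median 0.72, mean -0.01, adjusted p = 0.15), with a log2 fold change of 1.68 ± 0.32 for Fos.

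Outside the lists, the higher genes included log2 fold changes of 5.82 ± 0.62 for Gata2, 5.29 ± 0.23 for Pbk and 5.0 ± 0.27 for Kif20a, where Gata2 is a transcription factor. Scn7a was at least 78.8-fold lower and Rd3 was 458-fold lower, 95% counting interval 82.1 to 18100.0, with log2 fold changes of -7.15 ± 0.49 for Nrxn3 and -6.37 ± 0.41 for Piezo2, where Piezo2 is a mechanically gated channel. Adjusted over the list alone, higher and lower counts differed for catecholamine synthesis and transport (8 and 3), synaptic vesicle (3 and 10), neuroblastoma and paraganglioma genes (7 and 0), glial and neural crest genes (2 and 8), Notch pathway (0 and 9), glucocorticoid response genes (1 and 0) and dissociation stress genes (6 and 2). Under some of the 15 other settings, adjusted p was 0.05 or more, for Insm1, Rab3a, Vip, Sparc and Mapt under 1, Chrna3 and Pfkp under 2, Qdpr and Hoxb8 under 3, Rab3c under 4, Ret under 5 and Crmp1 under 7.

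Melanoblast-like cells were compared with Schwann cell precursor-like cells, as another fate of these glial progenitors, with 11 cells in replicate 1 and 6 in replicate 3. Melanoblast-like cells lacked much of the glial and matrix expression. Gpnmb, a melanosome glycoprotein, stood at 316 ± 41.0 CPM against 0 counts (at least 484-fold higher, adjusted p = 2.5e-05). Tyr, tyrosinase, was at 242 ± 185 CPM against 0 counts (at least 445-fold higher, adjusted p = 3.5e-04). Bace2 and Mt1 were higher too, with log2 fold changes of 8.08 ± 0.66 for Bace2 and 5.36 ± 0.44 for Mt1. The mm10 positions were Gpnmb (ENSMUSG00000029816) on chromosome 6 from 49036546 to 49070929 and Tyr (ENSMUSG00000004651) on chromosome 7 from 87424771 to 87493512. Of 6956 tested genes, 567 changed, 152 higher and 415 lower in melanoblast-like cells. The higher ones were 26.8% of these (23.7 to 50.4% under other settings).

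Glial and neural crest genes had 1 of 16 higher and 11 lower (median -4.50, or -2.86 at the bound, adjusted p = 1.8e-12). Ptprz1 was at least 35.4-fold lower, with log2 fold changes of -6.62 ± 0.82 for Fabp7 and -1.75 ± 0.37 for Zeb2, while Tfap2a had a log2 fold change of 1.93 ± 0.45. Basement membrane and matrix genes had 0 of 13 higher and 11 lower (median -3.48, adjusted p = 1.3e-13). Col4a2 was at least 39.3-fold lower, with a log2 fold change of -2.86 ± 0.82 for Sparc. Dissociation stress genes had 0 of 12 higher and 6 lower (median -4.57, or -2.51 at the bound, adjusted p = 8.8e-12). Egr1 was 50.8-fold lower, 95% counting interval 14.1 to 420.0, with log2 fold changes of -3.62 ± 0.57 for Fos and -2.60 ± 0.41 for Jun. Growth factor receptors had 0 of 14 higher and 6 lower (median -5.02, or -2.14 at the bound, adjusted p = 2.8e-06, adjusted p = 0.056 with an estimated correlation). Gfra3 was at least 28.0-fold lower, and Ednrb had a log2 fold change of -2.14 ± 0.57. The Notch pathway had 0 of 13 higher and 5 lower (median -5.67, or -1.46 at the bound, adjusted p = 3.9e-04, adjusted p = 0.071 with an estimated correlation). Hey2 was at least 4.27-fold lower, and Notch1 had a log2 fold change of -2.78 ± 0.53. Imprinted growth genes had 0 of 12 higher and 7 lower (median -3.09, or -3.17 at the bound, adjusted p = 2.3e-07, adjusted p = 0.090 with an estimated correlation), with log2 fold changes of -5.03 ± 0.73 for Mest and -3.17 ± 0.58 for Cdkn1c. Trunk Hox genes had 0 of 18 higher and 2 lower (median -8.10, or -0.25 at the bound, adjusted p = 9.5e-04, adjusted p = 0.10 with an estimated correlation). Hoxb9 was at least 9.24-fold lower. At most 3 counts in a class were seen for 15 Hox, 8 receptor and 7 Notch genes, so these tests may reflect depth. S phase genes had 1 of 15 higher and 0 lower (median 0.63, 0.10 and 0.96 per library, adjusted p = 2.8e-07, adjusted p = 0.081 with an estimated correlation), with a log2 fold change of 1.11 ± 0.21 for Mcm7. G2/M phase genes had 1 of 15 higher and 0 lower (median 0.31, 1.16 and 0.10 per library, adjusted p = 7.3e-04, adjusted p = 0.41 with an estimated correlation, reversed under 7 of 12 settings), with a log2 fold change of 1.16 ± 0.35 for Ccnb2. Hypoxia and glycolysis genes had 2 of 12 higher and 1 lower (median 0.06, mean -1.01, adjusted p = 0.29). Ldha had a log2 fold change of 0.92 ± 0.25, and Ddit4 was 23.9-fold lower, 95% counting interval 4.26 to 946.

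The catecholamine list had 0 of 12 higher and 0 lower (median -4.69, or -0.43 at the bound, adjusted p = 0.23). Dense-core vesicle genes had 1 of 14 higher and 1 lower (median -4.33, or -0.32 at the bound, adjusted p = 0.66), with log2 fold changes of 5.56 ± 0.82 for Syt4 and -2.93 ± 0.74 for Pam. Neurite cytoskeleton genes had 0 of 15 higher and 2 lower (median -2.12, or -1.29 at the bound, adjusted p = 0.070). Gap43 was 28.0-fold lower, 95% counting interval 7.74 to 232. Neuronal differentiation regulators had 1 of 15 higher and 0 lower (median -5.26, or 1.02 at the bound, test direction up, adjusted p = 0.38), with a log2 fold change of 1.02 ± 0.30 for Sox11. The synaptic vesicle list had 0 of 14 higher and 0 lower (median -4.27, or -0.13 at the bound, adjusted p = 0.67). Vamp2, at 15.9 ± 8.14 against 62.2 ± 27.3 CPM, did not pass. Ion channels and transmitter receptors had 0 of 14 higher and 0 lower (median -3.20, or 1.91 at the bound, test direction up, adjusted p = 0.77). Cacna1a, at 5.41 ± 7.65 against 15.4 ± 1.53 CPM, did not pass. Neuropeptide genes had 0 of 11 higher and 0 lower (median -3.63, or 1.71 at the bound, test direction up, adjusted p = 0.913). Npy, at 54.8 ± 8.59 against 85.9 ± 48.8 CPM, did not pass. Neuroblastoma and paraganglioma genes had 0 of 14 higher and 0 lower (median -0.29, or -0.26 at the bound, adjusted p = 0.77). Atrx, at 212 ± 1.41 against 305 ± 56.5 CPM, did not pass. Glucocorticoid response genes had 0 of 7 higher and 0 lower (median -3.57, or 0.74 at the bound, adjusted p = 0.913). Tsc22d3, at 37.2 ± 23.9 against 39.6 ± 2.74 CPM, did not pass.

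Genes outside the lists at 0 counts in melanoblast-like cells were lower by at least 24.7-fold for Cryab, 16.6-fold for Adgrg6, 18.4-fold for Zdhhc2 and 16.5-fold for Gas7. Adjusted over the list alone, higher and lower counts differed for dense-core vesicle secretion (1 and 4), neurite cytoskeleton (0 and 3), growth factor receptors (0 and 9), glial and neural crest genes (1 and 12), Notch pathway (0 and 9), basement membrane and matrix (0 and 12), trunk Hox genes (0 and 5), S phase genes (5 and 0), imprinted growth genes (1 and 9), hypoxia and glycolysis genes (3 and 1), glucocorticoid response genes (0 and 1) and dissociation stress genes (0 and 7). Under some of the 12 or 13 other settings that tested the gene, adjusted p was 0.05 or more, for Gpnmb, Tyr, Zeb2, Notch1, Mcm7, Ddit4, Syt4 and Gap43 under 1, Tfap2a under 2, Hey2 and Hoxb9 under 3, Sparc and Ldha under 5, Ednrb under 6, Sox11 under 7 and Ccnb2 under 8. Of simulated 2-fold changes, 13.4% were recovered, so smaller ones were mostly not detectable at this depth. Without the replicate block 308 genes changed.

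**Figure D3:**
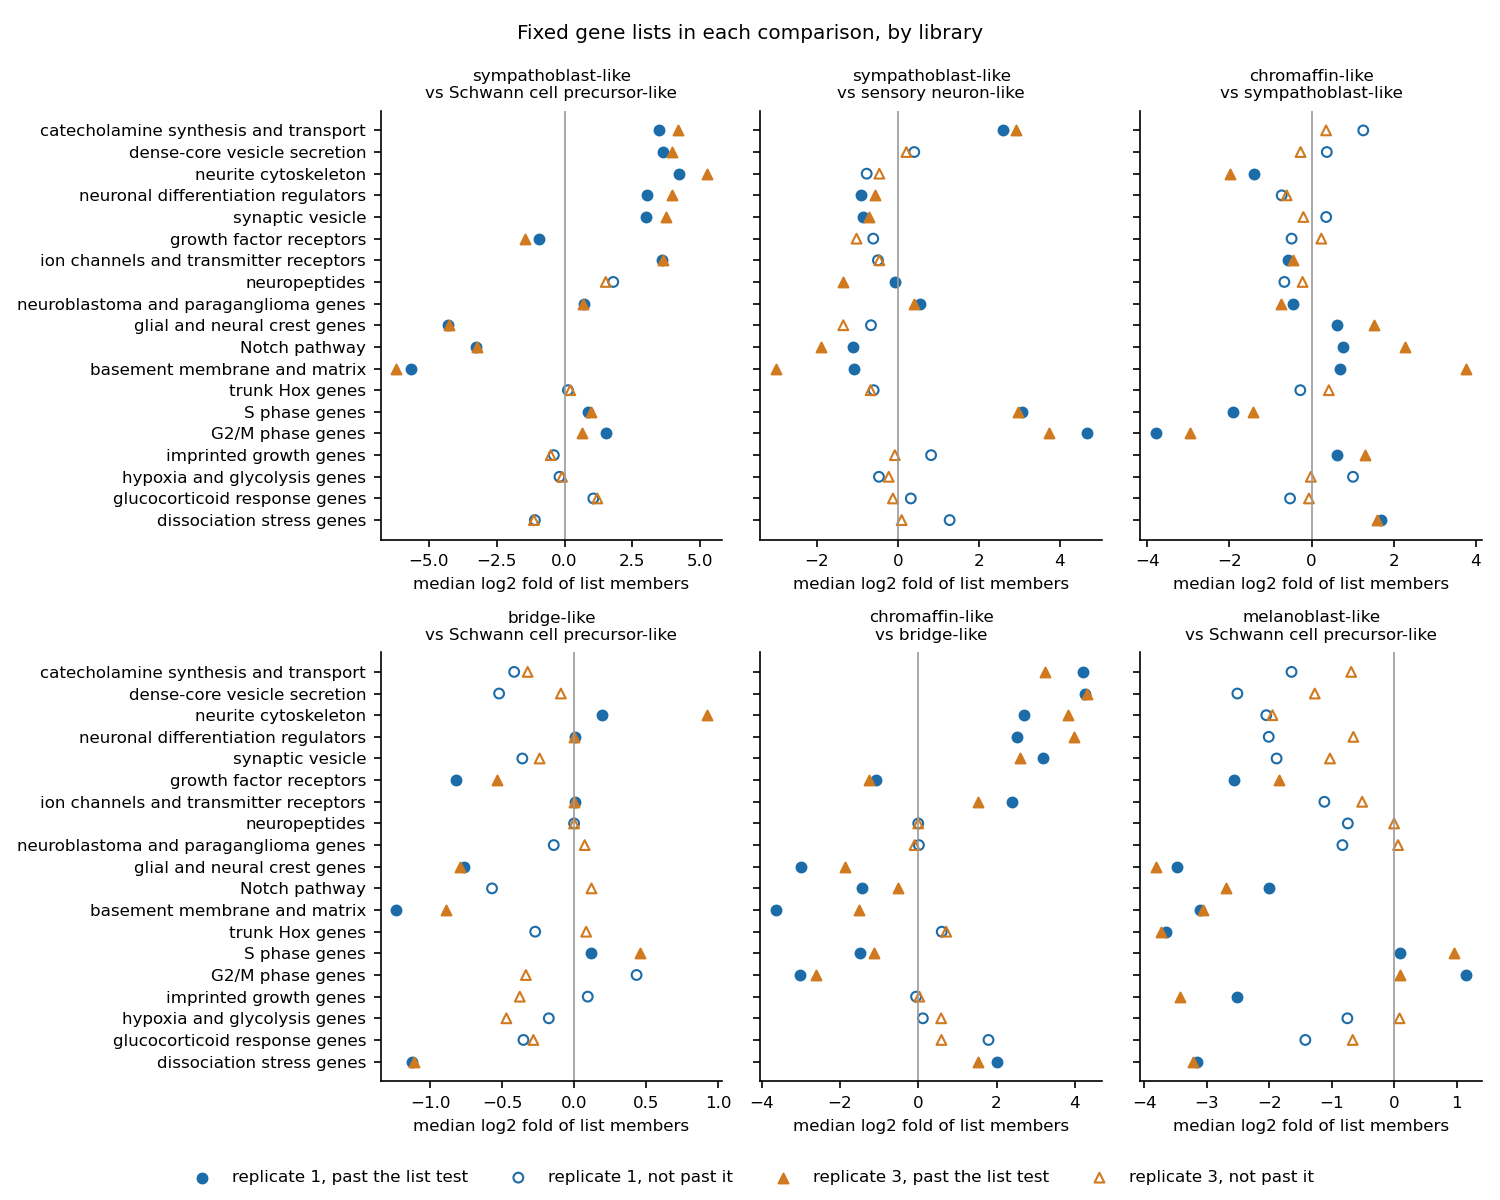
Median log2 fold change of the members of each of 19 gene lists in the 6 comparisons, in replicate 1 (circles) and replicate 3 (triangles), filled where the list passed the list test at the preset correlation. Values are log2 ratios of CPM plus 1, and S phase genes lie below 0 in chromaffin-like against sympathoblast-like cells and above 0 in sympathoblast-like against sensory neuron-like cells in both libraries.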

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

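Tests of all classes pooled were written before their results were seen, those of single classes after. The reporter appeared in data outside the comparisons: the classes outside the neural plate and crest held 45759 H2B-EGFP UMIs in 4153 cells of replicate 1 and 54715 in 1643 cells of replicate 3, above the 3 counts that a count of 0 allows. Free RNA, at 1028 and 1392 CPM, can pass that limit too, so these counts alone show no labelling. Against cells without the reporter that passed the sort, where a share below 50% of that in Schwann cell precursor-like cells at 3000 UMIs was predicted, the pooled share was 90.7% of it in replicate 3 and 92.9% in replicate 1. It was at least 96.1% in epithelium-like and 82.9% in mesenchyme-, cartilage-, mural- and skeletal muscle-like cells. Against transcript from free RNA alone, where at most 0.1 was predicted, the pooled reporter level was 0.758 times that of barcodes with at most 100 UMIs in replicate 3 and 1.49 times in replicate 1, at least 0.832 in epithelium-like cells and at least 0.591 in those 4 classes. The limit of 0.1 was low, since myeloid-like cells had 0.291 in replicate 1. The values argue against both explanations as the whole cause in these 5 classes. In the endothelium-, mesothelium-, nephron- and myeloid-like classes, with fewer than 20 cells in a library, values went down to 19.8% and 0.0791, and both explanations stay open. Which cells took up the virus stays open, and no biological explanation was tested.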

How the results depend on the processing

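Of 86 counts of changed genes under other settings with both libraries, 68 stayed within 1.5 times the reported count and 18 moved. For 86 counts of lists past the test these numbers were 80 and 6. Of 7006 values for named genes, 6253 kept direction and side of the threshold, 720 kept the direction but not the threshold and 33 reversed. Of 1627 list medians, 1436 stayed, 43 without a test moved, 41 came past the test, 69 no longer passed and 38 reversed. Of 190 shares of cells, 140 stayed and 50 moved, and all 10 for the crest classes together stayed as means of both libraries. With at most 5% mitochondrial UMIs the crest shares were 7.78% and 9.66%, against 14.3% and 8.32%. With 1 library left out, 266 of 970 values for named genes and 120 of 228 list medians moved, and named genes could not reverse by rule. Without the replicate block, changed genes in the order of the text were 2000, 13, 646, 611, 1262 and 308. In fits of only the 2 classes compared they were 495 for bridge-like against Schwann cell precursor-like, 862 for chromaffin-like against bridge-like and 1145 for chromaffin-like against sympathoblast-like cells. For bridge-like against Schwann cell precursor-like cells they were 333 with doublets retained, 805 with the odd genes, 525 at resolution 2, 440 with at least 1000 UMIs, 58 with mixed sub-clusters retained and 608 with the blood-cell filter off. For chromaffin-like against bridge-like cells they were 725 with at least 2000 detected genes, 671 with the odd genes and 550 at resolution 2. With an estimated correlation, the lists past the test were 2 for sympathoblast-like against sensory neuron-like, 2 for chromaffin-like against sympathoblast-like, 0 for bridge-like against Schwann cell precursor-like, 6 for chromaffin-like against bridge-like and 3 for melanoblast-like against Schwann cell precursor-like cells. With mixed sub-clusters retained, bridge-like against Schwann cell precursor-like cells had 4. With 1 library left out no test could be run, so changed genes with the same direction in the other library were counted, which says little of genes called from both, in the order of the text 3404 to 3408, 198 to 200, 1398 to 1431, 1826 to 1866, 2779 to 2783 and 561 to 567. Lists were 13, 6 to 8, 13, 10, 9 and 9, and the crest share was 8.32 to 14.3%. At most 5% mitochondrial UMIs left 463 and 642 cells, too few for the tests. DESeq2 gives no list test, no sub-clustering gives no bridge-like or melanoblast-like class, and a minimum of 10 cells gives no melanoblast-like comparison.

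These log2 fold changes of named genes reversed. In sympathoblast-like against Schwann cell precursor-like cells, Hoxb8 had 0.35 with at least 2000 detected genes, 0.76 with no sub-clustering and 0.81 with mixed sub-clusters retained. In sympathoblast-like against sensory neuron-like cells, Ntrk3 had -0.11 with resolution 2. In chromaffin-like against sympathoblast-like cells the values were -0.08 for Hoxb8 and -0.87 for Hoxb9 with at least 2000 detected genes. In bridge-like against Schwann cell precursor-like cells, Hoxa9 had 0.27 with resolution 2. In chromaffin-like against bridge-like cells the values were -0.05 for Tubb3, -0.91 for Mfng, -0.17 for Hoxa9 and 0.01 for Mki67 with the odd genes. With resolution 2 they were -0.07 for Elavl4, 2.96 for Gfra3, -1.20 for Mfng, -0.28 for Hoxa9, 1.28 for Mki67 and 0.30 for Mest. With at least 2000 detected genes they were 2.33 for Gfra3, -0.87 for Mfng, -0.52 for Hoxa9, 0.44 for Top2a, 1.48 for Ube2c, 2.17 for Mki67 and 0.05 for Mest. With no scaling within library they were 0.01 for Gfra3, -0.35 for Mfng, 0.00 for Top2a, 0.15 for Ube2c and 0.89 for Mki67. With doublets retained they were -0.06 for Mfng and 0.55 for Mki67. With at least 1000 UMIs they were -0.52 for Mfng and -0.33 for Hoxa9. These list medians reversed. In chromaffin-like against sympathoblast-like cells, trunk Hox genes had -0.85 with at least 2000 detected genes. In bridge-like against Schwann cell precursor-like cells the values were 0.04 for catecholamine, 0.20 for dense-core vesicle, 0.25 for synaptic vesicle and -3.15 for G2/M phase genes with at least 2000 detected genes. With doublets retained they were 0.20 for catecholamine, 0.36 for dense-core vesicle, 0.60 for synaptic vesicle and -2.40 for G2/M phase genes. With the odd genes they were 1.76 for catecholamine, 2.33 for dense-core vesicle, 1.38 for synaptic vesicle, -0.14 for S phase genes and -2.55 for G2/M phase genes. With resolution 2 they were 0.14 for catecholamine, 1.47 for dense-core vesicle, 1.18 for synaptic vesicle and -3.03 for G2/M phase genes. With at least 1000 UMIs they were 0.61 for catecholamine, 1.64 for dense-core vesicle, 0.98 for synaptic vesicle, 0.00 for S phase genes and -0.80 for G2/M phase genes. With mixed sub-clusters retained they were -0.69 for neurite cytoskeleton, -0.69 for differentiation regulators and -0.04 for ion channels. With no scaling within library they were 0.02 for dense-core vesicle and -2.96 for G2/M phase genes. With the blood-cell filter off they were -0.20 for differentiation regulators and 0.55 for hypoxia and glycolysis genes. In chromaffin-like against bridge-like cells, G2/M phase genes had 0.44 with at least 2000 detected genes. In melanoblast-like against Schwann cell precursor-like cells, G2/M phase genes had -0.24 with at least 2000 detected genes, -0.67 with doublets retained, -0.41 with the odd genes, -0.28 with resolution 2, -0.36 with at least 1000 UMIs, -0.19 with mixed sub-clusters retained and -0.27 with no scaling within library. The cause was not tested for any of these values, and depth limits the bridge-like, chromaffin-like and melanoblast-like comparisons most, with 10, 13 and 6 cells in replicate 3.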

Other observations

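The tests of the share of epithelium-like cells were chosen after that share was seen, and those of the stress genes before. The descriptions of clusters were made after their values were seen. Chromaffin-like cells fell into a sub-cluster led by Chgb, Ndufa4l2 and Th, with 184 cells in replicate 1 and 6 in replicate 3, and another led by Cck, Penk and Dll3, with 48 and 7. Sympathoblast-like cells fell into one led by Prph, Nefm and Stmn2, with 93 and 50 cells, one led by the cell cycle genes Rrm2 and Pbk, with 113 and 29, and one led by Slc18a3, Prph and Sst, with 22 and 1. Globin made up 128 UMIs in epithelium-like cells of replicate 1 and 48048 in replicate 3, where 98.8% were in 2 cells.

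Epithelium-like cells were 11.8% of replicate 1 and 32.4% of replicate 3. They mostly lay in different clusters, one with 722 and 0 cells of replicates 1 and 3 and one with 55 and 629, while another had 96 and 116. With 1 UMI minimum of 1000 for both libraries the shares were 9.65% and 28.6%, a difference of 19 percentage points, which argues against the different minimums as the whole cause. At resolution 2 the shares were 11.1% and 17.7%, since 335 cells of replicate 3, 14.6%, took the erythroid name, and with the cells of that name they were 11.5% and 32.3%. Of the 335, 99.1% had a Krt5 UMI, against 15.4% of cells of other names, and their median was 0 globin UMIs, which argues against erythroid cells as the source of the gap. Epithelium-like, unnamed and mixed cells of replicate 1 together made up 22.3%, below the lower bound of 30.5% in replicate 3, which argues against epithelial cells hidden among them. Differences in dissection or in the injected embryos stay open, and no biological explanation was tested.

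Dissociation stress genes were higher in chromaffin-like than in sympathoblast-like cells at the preset correlation, with an adjusted p = 0.17 with an estimated correlation. Of the 10 raised members, 7 had a chromaffin-like CPM above that of barcodes with at most 100 UMIs in both libraries, where free RNA would give fewer than 5. Damaged cells stay open: the median mitochondrial share of chromaffin-like minus sympathoblast-like cells was -0.106 percentage points in replicate 1 and 0.447 in replicate 3, which differ in sign. No biological explanation was tested.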
